A study of Homo sapiens with 12 samples.

How the data were processed

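RNA was measured by strand-specific, polyA+ RNA-seq (dUTP marking of the second strand, per the labels' protocols) in U-2932, a human diffuse large B cell lymphoma line. The cells stably expressed Roquin2 in its wild-type form (WT) or with the Y691F substitution. They were left untreated or given F(ab')2-IgM, which engages the B cell receptor, at 10 µg/ml for 12 h. Each of the 4 groups held 3 libraries, described by the submitters as independent biological replicates. Whether each Roquin2 form was present in 1 or in several independently made lines is not given in the sources used here.

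The deposited table gave, per the file headers, a read count and an RPKM value for each of 60675 Ensembl genes in each of the 12 libraries. The counts deposited by the authors were whole numbers. The RPKM values deposited by the authors were 0 exactly where the count was 0, and they were not used here. STAR 2.5.0b, DESeq2 and the GRCh38 build are named in the submitters' processing notes, without the version of DESeq2. The read counter, its settings and the annotation release are not given in the sources used here. Gene symbols, Ensembl identifiers and coordinates (GRCh38, 1-based) were taken from the file. In the file, 1847 symbols occur more than once, and genes were therefore handled by identifier.

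The library totals ran from 16465393 to 21478790 counts. Of the genes, 30061 had a count in at least 1 library and 15112 passed the filterByExpr function of edgeR and were tested. Counts were scaled with TMM factors. The quasi-likelihood test of edgeR 4.0.16 with robust fitting (R 4.3.3) was applied to all 12 libraries with 1 coefficient per group and no covariate, so that the groups shared the estimate of the spread. The contrasts were Y691F against WT with IgM, Y691F against WT untreated, IgM against untreated in WT, IgM against untreated in Y691F, and the difference between both IgM responses (the interaction). In each contrast p was adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Unless stated otherwise, p is 2-sided and adjusted p for a gene is from this test. Levels are CPM, counts scaled by the TMM-adjusted library total, given as mean ± SD with n = 3 libraries per group. Fold changes are on the log2 scale with an approximate standard error (SE). This SE was the size of the log2 change divided by the square root of the F statistic of the quasi-likelihood test.

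The 24 gene lists covered reported Roquin targets, NF-kB targets, immediate early genes, ribosome biogenesis, G1/S and replication, G2/M and mitosis, p53 targets, the BCL2 family and interferon response. They also covered cholesterol synthesis, glycolysis and hypoxia, the unfolded protein response, germinal center, plasma cell, B cell receptor signalling, MHC class II, cytokines with their receptors, and mRNA decay factors. The rest were mitochondrial mRNAs, replication histones, cytosolic ribosomal proteins, and markers of T and NK cells, of myeloid cells, and of fibroblasts and epithelium. They were tested with camera of limma 3.58.1 on log-CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over all lists and contrasts together. Lists with at least 5 tested members entered, which left out the myeloid and the fibroblast and epithelial markers. The same test with the correlation estimated from the data, and fry, were alternatives. Members were also counted from the test over all genes and after adjustment within the list.

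The design, the gene lists, the alternatives and the rule for naming genes were written before the data were examined. The rule took genes with an adjusted p under 0.05, with the 3 libraries of one group all above the 3 of the other, a mean of at least 1 CPM and a symbol that is not a clone or pseudogene name. From these came the 10 largest rises and 10 largest falls for Y691F against WT with IgM and for IgM in WT, and the 5 largest of each elsewhere, without the condition on separated libraries for the interaction. RC3H2, RC3H1, TNFAIP3 and KLHL6 were always named, and up to 4 members of each list with the smallest adjusted p could be. Some genes that met the rule are not reported here. In the interaction, KCNA2 met the rule among the falls but had no read in Y691F with IgM, so it was left out of that comparison. Every called gene named in a contrast between groups of libraries had its 3 libraries of one group all above the other 3. This was the case for 50 of 50, 36 of 36, 64 of 64 and 34 of 34 genes in the order of the contrasts given above. Where a group had no read for a gene, the fold is a lower bound against 3 counts over the group. Where it had 1 to 3 reads, the ratio is given with its 95% interval. Such intervals and bounds cover counting error only.

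Other choices tried were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, no filter on low counts, a filter of 5 CPM in 3 libraries, and the replicate number as a block. Others were the barcode series in the library descriptions as a covariate, only the 7 libraries of barcode series b, only the groups compared, a minimum fold of 1.2, and leaving out each library in turn. Scaling by library totals only was added after the data were seen. The tests of explanations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. For the 3' UTRs and GC content, GENCODE v29 transcripts (GRCh38) were matched by Ensembl identifier.

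The test was tried on simulated counts with the real library sizes and 1 mean per gene over all 12 libraries, with 200 of 15112 genes changed. For Y691F against WT with IgM, it found 27, 40, 37 and 50 of 50 genes changed by 1.2, 1.5, 2 and 4-fold, with 2 calls among the unchanged genes and 14722 genes in the test. For Y691F against WT untreated (14734 genes), it found 28, 43, 46 and 50, with 10 false calls. For IgM in WT (14727 genes) the numbers were 32, 41, 47 and 47, with 17 false calls, and for IgM in Y691F (14733 genes) 27, 39, 47 and 49, with 10. For the interaction (14719 genes) they were 17, 30, 38 and 45, with 5. A list shifted on purpose was recovered in all 5 contrasts, and 1 of 20 unshifted lists was called in IgM against untreated in WT and 0 in the other contrasts. In the data 25.7% to 76.9% of the tested genes were called, so the scaling was not tried under changes that broad. The simulated genes were drawn independently, so the preset correlation was not tried either.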

Results

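The table of counts covered 12 libraries in 4 groups of 3: WT untreated, WT with IgM, Y691F untreated and Y691F with IgM. The total counts per library were 16496168 to 21478790 in WT untreated and 16465393 to 19392749 in WT with IgM. They were 18390011 to 20431651 in Y691F untreated and 16754981 to 19674442 in Y691F with IgM. Mitochondrial genes took 7.63% to 8.82% of the counts. The first principal component of log-CPM held 78.1% of the variance and parted the untreated from the IgM libraries, and the second held 9.91% and parted WT from Y691F. The biological coefficient of variation among replicates was 2.51%. Between 2 replicates of a group, counts varied 1.43 to 2.42 times as much as counting error alone (chi-square over degrees of freedom). The p-values rest on this small spread between libraries. Whether it covers a spread between independently made lines is not given in the sources used here. The TMM factors were 1.04 to 1.07 in the untreated libraries and 0.939 to 0.956 with IgM. With library totals only, the median log2 change over all tested genes moved by -0.13 for IgM in WT and by -0.17 for IgM in Y691F, and the IgM responses below are relative to the TMM scaling.

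Roquin2, encoded by RC3H2, is an RNA-binding protein that promotes the decay of mRNAs with stem-loops in their 3' UTR, and RC3H1 encodes its paralog. KLHL6 encodes the substrate adaptor of a ubiquitin ligase of B cells, and TNFAIP3 encodes A20, a deubiquitinase that restrains NF-kB signalling and whose mRNA is a reported Roquin target. RC3H2 (ENSG00000056586, chromosome 9, 122844556 to 122905341, minus strand) stood at 111 ± 1.08 CPM in WT and 209 ± 0.880 CPM in Y691F without IgM (log2 0.92, SE 0.03, 1.89-fold, adjusted p = 2.50e-41). With IgM it stood at 121 ± 1.80 and 206 ± 1.79 CPM (log2 0.77, SE 0.03, adjusted p = 7.31e-36). Whether reads from the introduced construct were counted on RC3H2 is not given in the sources used here, and the level in cells without a construct was not measured. The Roquin2 form and the RC3H2 mRNA level therefore differed together between the lines, and the dose of Roquin2 protein was not measured. RC3H2 rose with IgM by 0.13 in WT (adjusted p = 4.95e-04), a call that was absent with library totals only (-0.0051, adjusted p = 0.894), and no change was called in Y691F (-0.020, adjusted p = 0.556). In Y691F a fall was called with library totals only (-0.19, adjusted p = 4.16e-08) and with a filter of 5 CPM (-0.074, adjusted p = 0.0182), so this result depended on the scaling and the filter, and over all alternatives its adjusted p ran from 4.16e-08 to 1. TNFAIP3 (ENSG00000118503, chromosome 6, 137867188 to 137883312, plus strand) stood at 38.6 ± 2.37 CPM in untreated WT and 41.4 ± 1.01 CPM in untreated Y691F (log2 0.093, adjusted p = 0.143). With IgM it reached 147 ± 3.61 CPM in WT and 72.6 ± 1.44 CPM in Y691F, 2.02-fold lower in Y691F (log2 -1.01, SE 0.04, adjusted p = 6.91e-39). RC3H1 (ENSG00000135870, chromosome 1, 173931214 to 174022297, minus strand) was higher in untreated Y691F (46.3 ± 4.04 against 33.2 ± 0.669 CPM, log2 0.48, adjusted p = 3.06e-11). With IgM its levels were 63.3 ± 1.46 and 63.1 ± 5.45 CPM, and no difference was called (log2 0.0031, adjusted p = 0.968). KLHL6 (ENSG00000172578, chromosome 3, 183487531 to 183555689, minus strand) was lower in untreated Y691F (393 ± 8.31 against 539 ± 12.5 CPM, log2 -0.46, adjusted p = 3.02e-25) and higher with IgM (406 ± 10.7 against 329 ± 4.63 CPM, log2 0.30, adjusted p = 2.60e-15).

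**Figure D1:**
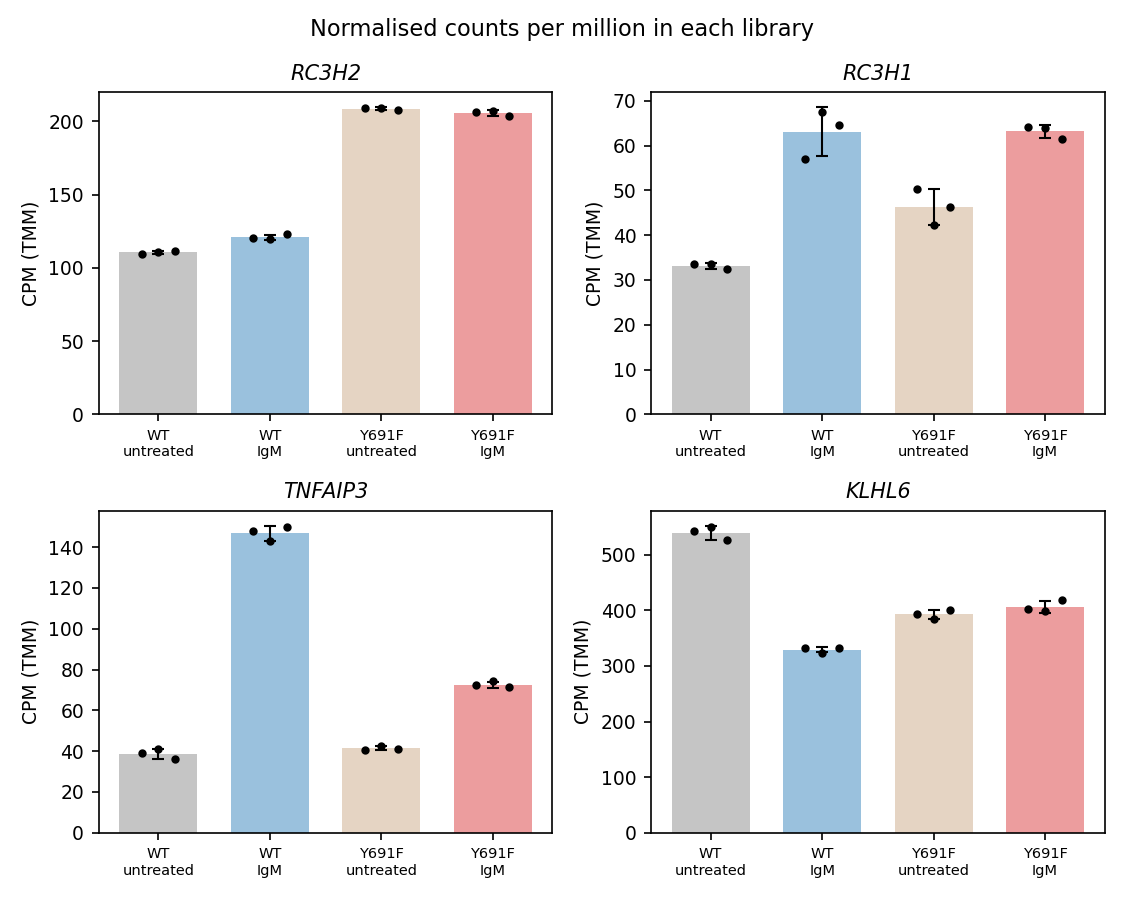
Levels of RC3H2, RC3H1, TNFAIP3 and KLHL6 in CPM (TMM-scaled) in the 4 groups, where bars are means, points are the 3 libraries and error bars are the SD. TNFAIP3 stood at 147 CPM in WT with IgM and 72.6 CPM in Y691F with IgM, and RC3H2 at 111 and 209 CPM in the untreated lines.

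The comparison of Y691F with WT under IgM asked what the substitution changed in mRNA levels when the B cell receptor was stimulated. TNF and LTA encode secreted cytokines, and NFKBIE, NFKBIZ and NFKBID encode proteins of the IkB family that act on NF-kB. Lower in Y691F were LTA (-1.77, adjusted p = 8.87e-51), TNF (-1.36, adjusted p = 6.28e-38), NFKBIZ (-1.59, adjusted p = 5.14e-49) and NFKBIE (-0.93, adjusted p = 7.42e-45). LTA stood at 32.5 ± 0.231 CPM in Y691F and 111 ± 5.23 CPM in WT, and TNF at 24.7 ± 1.69 and 63.8 ± 1.35 CPM. ZC3H12A, which encodes the endonuclease Regnase-1, was also lower (51.3 ± 1.83 against 129 ± 2.22 CPM, log2 -1.33, SE 0.04, adjusted p = 3.51e-46). The chemokine receptor gene CCR7 was lower too (393 ± 5.65 against 975 ± 21.9 CPM, log2 -1.31, SE 0.03, adjusted p = 2.44e-57). Of the 29 measured NF-kB targets, 7 were higher and 17 lower (7 and 17 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.0101, adjusted p = 0.177 with an estimated correlation). The reported Roquin targets, of which 4 are also on the NF-kB list, were 1 higher and 9 lower of 13 (1 and 9 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 9.56e-05, adjusted p = 0.0842 with an estimated correlation). Among immediate early genes, which are transcribed within minutes of receptor signalling, EGR1 was lower (-1.10, adjusted p = 1.32e-47) and NR4A1 higher (0.72, adjusted p = 1.01e-35). Their list counted 7 higher and 13 lower of 24 (7 and 13 adjusted over the list alone, camera adjusted p = 0.0269, adjusted p = 0.302 with an estimated correlation), and the call was lost without replicate 3 of WT with IgM (0.0510). The cytokines and their receptors were 7 higher and 9 lower of 23 (7 and 10 adjusted over the list alone, camera adjusted p = 0.296). TNFRSF1B, a TNF receptor gene, was higher (186 ± 1.98 against 62.6 ± 3.88 CPM, log2 1.56, SE 0.04, adjusted p = 3.79e-49).

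Genes of cholesterol synthesis and uptake were higher in Y691F with IgM. SQLE stood at 587 ± 22.9 against 224 ± 3.10 CPM (log2 1.39, SE 0.03, adjusted p = 6.76e-57), and HMGCS1 was higher by 1.21. The list counted 19 higher and 1 lower of 21 (19 and 1 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 2.81e-12, adjusted p = 0.0340 with an estimated correlation). It was the only one of the 22 tested lists whose call in this comparison held with that estimate. The hypoxia-responsive genes VEGFA (-1.26), ADM (-1.21) and the glucose transporter gene SLC2A1 (-0.74) were lower. Glycolysis and hypoxia genes counted 3 higher and 20 lower of 26 (3 and 20 adjusted over the list alone, camera adjusted p = 8.50e-07, adjusted p = 0.188 with an estimated correlation). In the plasma cell list, MZB1 (1.16) and PRDM1 (0.92) were higher and SLAMF7 (-0.79) was lower. The list counted 11 higher and 3 lower of 17 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00503, adjusted p = 0.110 with an estimated correlation). Among germinal center genes, CD38 (1.35) and CD27 (1.45) were higher. That list counted 11 higher and 5 lower of 21 (11 and 5 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.141 with an estimated correlation). In B cell receptor signalling, the inhibitory coreceptor gene CD22 was lower (-1.10), while PLCG2 (0.60) and the kinase gene BLK (0.88) were higher. The pathway counted 14 higher and 8 lower of 31 (17 and 8 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.163 with an estimated correlation). HLA-DQB1 (-0.77) and HLA-DRB1 (-0.28) were lower. MHC class II genes counted 2 higher and 10 lower of 15 (2 and 10 adjusted over the list alone, camera adjusted p = 0.00290, adjusted p = 0.177 with an estimated correlation), though HLA genes can share reads. IRF7 (1.41) of the interferon response was higher, without a call for the list (7 higher and 3 lower of 16, with 8 and 4 adjusted over the list alone, camera adjusted p = 0.0710). Of the 16 T and NK cell markers on the list only 5 passed the filter on low counts, so most of the set was too low to test. Those 5 counted 4 higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.0265, adjusted p = 0.141 with an estimated correlation).

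By size of change, the largest rises in Y691F over WT with IgM were in genes with low levels in WT. LRRN3 stood at 7.18 ± 0.785 against 0.212 ± 0.0750 CPM (log2 5.01). FST, the gene of the activin antagonist follistatin (ENSG00000134363, chromosome 5, 53480409 to 53487134, plus strand), stood at 32.4 ± 2.12 against 2.14 ± 0.302 CPM (log2 3.92, SE 0.11, adjusted p = 3.81e-49). The axon guidance receptor gene ROBO1 (3.41), GPR171 (3.14), ARAP3 (3.68), DLGAP1 (3.13) and the perforin gene PRF1 (3.55) were also higher. NCAM1 was higher by 4.95 and P2RY2 by 3.70, and without replicate 2 of WT with IgM, which left 1 read of each in WT, their ratios were 85.3 (15.1 to 3392) and 60.6 (10.6 to 2416). SEMA6A had 2 reads in WT with IgM and a ratio of 52.9 (14.3 to 443). The largest falls included the inducible heat shock gene HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910, plus strand), at 0.321 ± 0.0620 against 25.4 ± 1.503 CPM (log2 -6.26, adjusted p = 9.48e-49). HSPB1 stood at 1.65 ± 0.228 against 17.9 ± 1.63 CPM (log2 -3.42). HSPA6 has a near-identical pseudogene that can share its reads. TNFRSF14, the gene of the receptor HVEM, was lower at 12.7 ± 1.004 against 84.2 ± 2.10 CPM (log2 -2.72, adjusted p = 5.82e-55). So were the hypoxia-inducible lipid droplet gene HILPDA (-3.29) and TNNI1 (-2.78). With 2 or 3 reads in Y691F with IgM, the ratios of WT over Y691F were 97.3 (26.6 to 809) for LILRA6, 69.5 (18.9 to 579.7) for LILRB3 and 48.7 (16.3 to 239) for ZNF385C. All 3 reads of ZNF385C lay in replicate 2 of Y691F with IgM, without which WT was at least 31.4-fold higher. For DNAH2 the ratio was 39.5 (13.2 to 194), or 82.8 (14.6 to 3297) without replicate 3 of Y691F with IgM. LILRA6 and LILRB3 are close relatives that can share reads.

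In all, 3305 genes were higher and 3057 lower in Y691F with IgM, of which 491 and 197 changed at least 2-fold. The median size of the called changes was 0.31 on the log2 scale. No list call was made for ribosome biogenesis (7 higher and 12 lower of 29, with 7 and 12 adjusted over the list alone, camera adjusted p = 0.367). G1/S and replication genes were not called (8 higher and 5 lower of 26, with 9 and 5 adjusted over the list alone, camera adjusted p = 0.670), nor were G2/M and mitosis genes (6 higher and 3 lower of 25, with 6 and 3 adjusted over the list alone, camera adjusted p = 0.670). The same held for p53 targets (8 higher and 8 lower of 22, with 8 and 9 adjusted over the list alone, camera adjusted p = 0.955). It also held for the BCL2 family (3 higher and 7 lower of 14, with 5 and 7 adjusted over the list alone, camera adjusted p = 0.272). The mRNA decay factors gave no call (9 higher and 10 lower of 32, with 9 and 10 adjusted over the list alone, camera adjusted p = 0.813). The unfolded protein response was not called either (4 higher and 9 lower of 23, with 4 and 9 adjusted over the list alone, camera adjusted p = 0.0710), with DDIT3 at -1.09. Mitochondrial mRNAs counted 4 higher and 0 lower of 13 (4 and 0 adjusted over the list alone, camera adjusted p = 0.724). Calls that did not hold without 1 library were made for cytosolic ribosomal proteins and replication histones. Cytosolic ribosomal protein genes were 4 higher and 14 lower of 30 (4 and 15 adjusted over the list alone, camera adjusted p = 0.0279, adjusted p = 0.654 with an estimated correlation), with RPL11 at -0.33, a call lost without replicate 1 of Y691F with IgM (0.0902) or replicate 2 of Y691F with IgM (0.0655). Replication histone genes were 5 higher and 0 lower of 12 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0448, adjusted p = 0.430 with an estimated correlation), with HIST1H2BK at 0.52, and their call was lost without replicate 2 of WT with IgM (0.103), replicate 3 of WT with IgM (0.0506), replicate 1 of Y691F with IgM (0.0899) or replicate 2 of Y691F with IgM (0.0715). The single tested myeloid marker, of 15 on the list, was higher. Of 4 tested fibroblast and epithelial markers, from 14 on the list, 1 was higher and 0 lower (1 and 0 adjusted over the list alone). Because each Roquin2 form came with its own stable cells, the difference between the forms cannot be told from other differences between these cells.

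**Figure D2:**
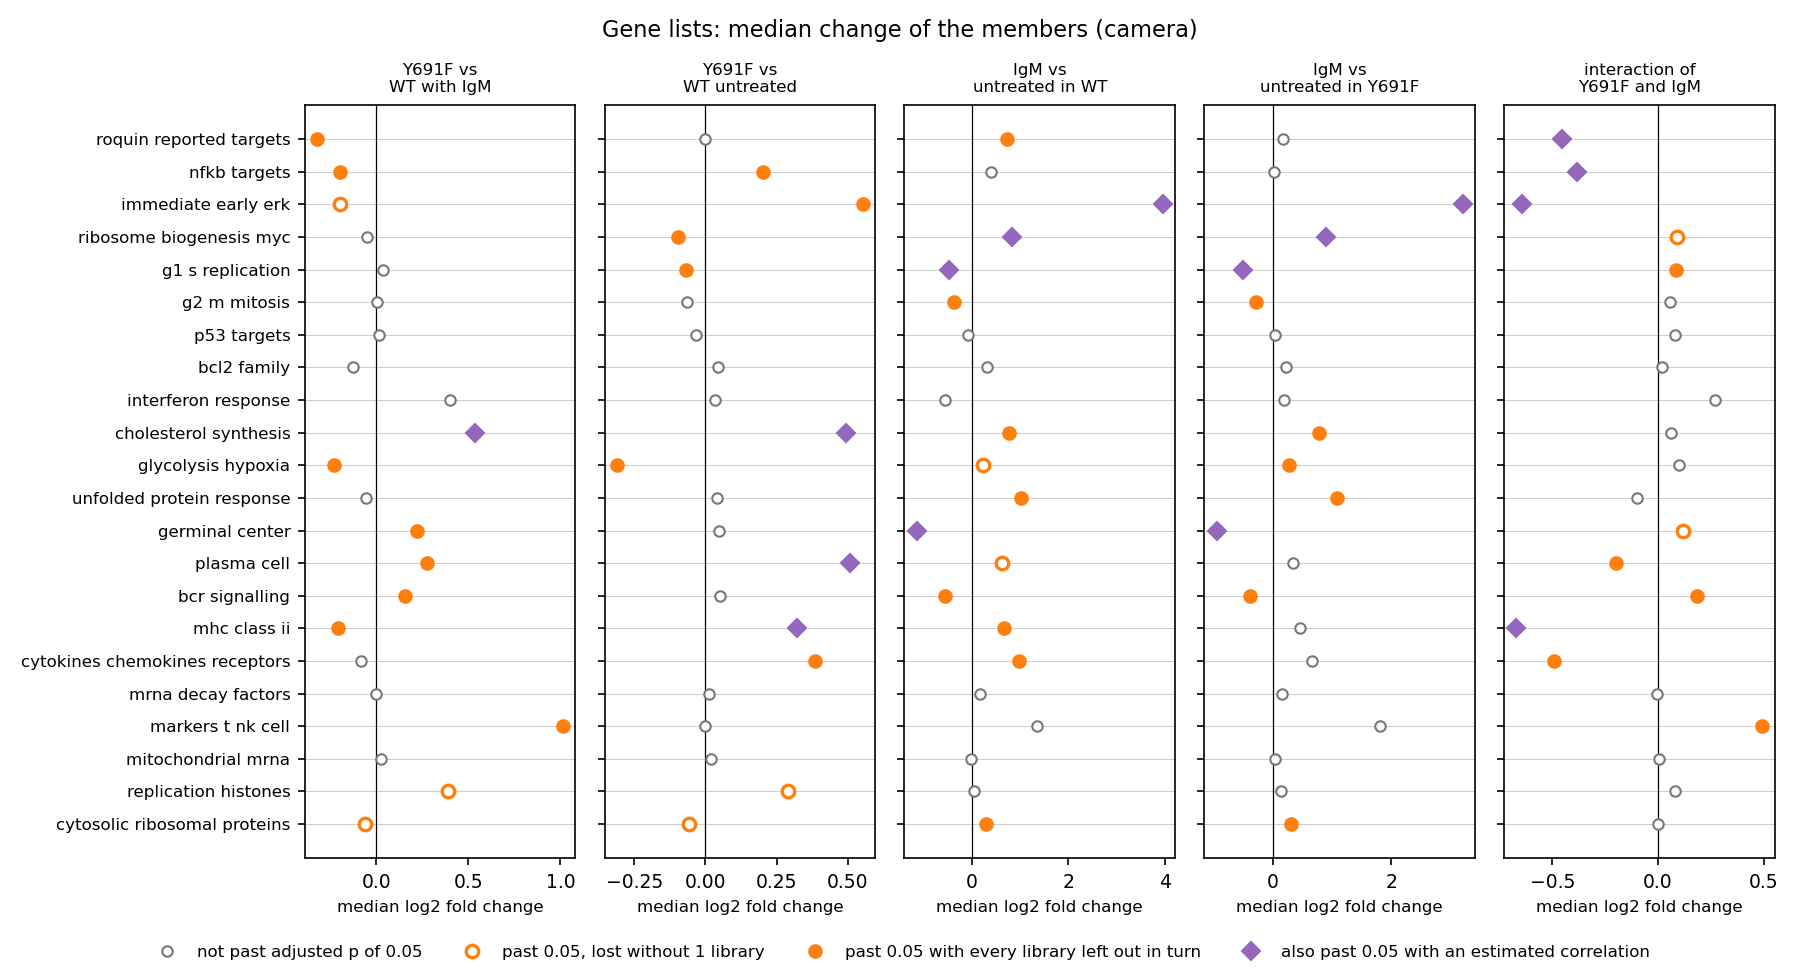
Median log2 fold change of the tested members of 22 gene lists (horizontal axes) in the 5 contrasts, with grey open circles where the camera adjusted p was 0.05 or more, orange open circles where a call was lost without 1 library, orange filled circles for other calls, and purple diamonds for calls that held with an estimated correlation. Cholesterol synthesis had medians of 0.54 with IgM and 0.49 untreated for Y691F against WT, and MHC class II a median of -0.67 in the interaction.

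The comparison of the untreated lines gave the background against which the stimulated cells were read. The NR4A and EGR genes encode transcription factors induced by receptor signalling, and INSIG1 is a sterol-regulated gene. Higher in untreated Y691F were NR4A1 (1.38, adjusted p = 1.46e-40), NR4A3 (2.17, adjusted p = 4.11e-28) and EGR1 (1.29, adjusted p = 2.42e-24). Immediate early genes counted 13 higher and 4 lower of 24 (15 and 4 adjusted over the list alone, camera adjusted p = 4.72e-05, adjusted p = 0.0902 with an estimated correlation). In the cholesterol list INSIG1 (1.04), HMGCS1 (0.84) and DHCR7 (0.72) were higher. The list counted 20 higher and 0 lower of 21 (20 and 0 adjusted over the list alone, camera adjusted p = 6.91e-19, adjusted p = 0.0126 with an estimated correlation). Every plasma cell gene measured was higher (17 higher and 0 lower of 17, with 17 and 0 adjusted over the list alone, camera adjusted p = 1.45e-15, adjusted p = 0.00842 with an estimated correlation). SLAMF7 stood at 47.5 ± 1.32 against 20.9 ± 0.737 CPM (log2 1.18). CREB3L2 (0.85), MZB1 (0.75) and the transcription factor gene IRF4 (0.51) were higher. MHC class II genes were 12 higher and 0 lower of 15 (12 and 0 adjusted over the list alone, camera adjusted p = 1.94e-09, adjusted p = 0.0427 with an estimated correlation), with HLA-DQA1 at 0.68 and HLA-DRA at 0.53. NF-kB targets were 18 higher and 4 lower of 29 (19 and 5 adjusted over the list alone, camera adjusted p = 2.87e-05, adjusted p = 0.0610 with an estimated correlation). In that list CD83 (0.54) and BCL2A1 (0.51) were higher, whereas TNFAIP2 (-2.32) and NFKBIZ (-1.19) were lower. Cytokines and their receptors counted 14 higher and 3 lower of 23 (15 and 4 adjusted over the list alone, camera adjusted p = 3.78e-07, adjusted p = 0.0550 with an estimated correlation), with TNFRSF1B at 1.76 and TNF at 0.66. Lower in untreated Y691F were VEGFA (-1.91), ALDOC (-0.93) and BNIP3 (-0.82). Together, glycolysis and hypoxia genes counted 1 higher and 21 lower of 26 (1 and 22 adjusted over the list alone, camera adjusted p = 6.37e-13, adjusted p = 0.0842 with an estimated correlation). Ribosome biogenesis genes were 0 higher and 17 lower of 29 (0 and 19 adjusted over the list alone, camera adjusted p = 4.06e-05, adjusted p = 0.0902 with an estimated correlation), FBL among them at -0.24. G1/S genes were 0 higher and 10 lower of 26 (0 and 12 adjusted over the list alone, camera adjusted p = 0.00271, adjusted p = 0.146 with an estimated correlation), with E2F1 at -0.23.

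The largest rises in untreated Y691F were NXN, at 3.13 ± 0.246 against 0.170 ± 0.00974 CPM (log2 4.15, adjusted p = 1.08e-19), and C14orf132 (3.45), PRKD1 (3.09) and HSPG2 (2.72). They also included the chemokine gene CCL4 (2.66), which can share reads with its copies. Among the largest falls were ZNF385C (-4.59), POU3F1 (-3.12) and the G protein gene GNAZ, at 2.85 ± 0.144 against 39.7 ± 0.489 CPM (log2 -3.79). DNAH2 had 3 reads in untreated Y691F, and WT exceeded it by a ratio of 64.6 (21.8 to 316), or 125 (22.1 to 4949) without replicate 1 of untreated Y691F. A total of 2279 genes were higher and 2437 lower, of which 287 and 129 changed at least 2-fold. The reported Roquin targets counted 5 higher and 4 lower of 13 (5 and 4 adjusted over the list alone) without a call (camera adjusted p = 0.507). Replication histone genes counted 5 higher and 0 lower of 12 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.352 with an estimated correlation), with HIST1H1C at 0.67, a call lost without replicate 3 of Y691F untreated (0.0661). For cytosolic ribosomal protein genes, 2 higher and 11 lower of 30 (2 and 13 adjusted over the list alone, camera adjusted p = 0.0287, adjusted p = 0.654 with an estimated correlation), the call was lost without replicate 2 of WT untreated (0.0575), replicate 1 of Y691F untreated (0.175) or replicate 3 of Y691F untreated (0.0822).

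The response of WT cells to IgM is the reference for what stimulation does in these cells. Cross-linking of the B cell receptor induces immediate early genes through ERK and calcium signals, and MYC-driven growth can raise ribosome biogenesis. Whether these routes led to the changes below was not tested. EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315, plus strand) rose from 7.43 ± 0.540 to 716 ± 11.9 CPM (log2 6.59, SE 0.05, adjusted p = 1.19e-89), NR4A1 by 4.57 and NR4A3 by 6.87. Immediate early genes counted 23 higher and 1 lower of 24 (23 and 1 adjusted over the list alone), with a median of 3.96 (camera adjusted p = 1.06e-09, adjusted p = 0.0417 with an estimated correlation). All measured ribosome biogenesis genes rose (29 higher and 0 lower of 29, with 29 and 0 adjusted over the list alone, camera adjusted p = 4.34e-10, adjusted p = 0.0417 with an estimated correlation), among them LYAR (1.47), DDX21 (1.21) and NPM1 (1.15). The chaperones HSPA5 (2.26) and HSP90B1 (2.76) and the stress factor gene DDIT3 (3.87) rose. The unfolded protein response counted 19 higher and 4 lower of 23 (19 and 4 adjusted over the list alone, camera adjusted p = 1.81e-05, adjusted p = 0.242 with an estimated correlation). NFKB1 rose by 2.25, NFKBIE by 2.62 and CD83 by 2.12. The NF-kB list went both ways (17 higher and 11 lower of 29, with 17 and 11 adjusted over the list alone, camera adjusted p = 0.113). REL (1.98) and NFKBID (1.57) rose among reported Roquin targets. These counted 12 higher and 1 lower of 13 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.134 with an estimated correlation). TNFAIP3 rose by 1.92 (adjusted p = 5.72e-58), RC3H1 rose by 0.93 and KLHL6 fell by 0.71 (adjusted p = 1.33e-38). The antiapoptotic gene BCL2 rose from 695 ± 3.17 to 2916 ± 47.6 CPM (log2 2.07). The BCL2 family as a list was not called (8 higher and 6 lower of 14, with 8 and 6 adjusted over the list alone, camera adjusted p = 0.335). The mRNA decay genes ZFP36L1 (2.77) and ZC3H12C (3.08) rose, again without a call for the list (20 higher and 11 lower of 32, with 20 and 11 adjusted over the list alone, camera adjusted p = 0.163).

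Germinal center and proliferation genes fell in WT with IgM. BCL6, a repressor that keeps B cells in the germinal center state, fell from 553 ± 10.0 to 125 ± 2.76 CPM (log2 -2.14, adjusted p = 4.53e-71). CD27 (-3.54) and CD38 (-1.82) fell too, and the list counted 4 higher and 16 lower of 21 (4 and 16 adjusted over the list alone, camera adjusted p = 9.28e-04, adjusted p = 0.04998 with an estimated correlation). Genes of the receptor pathway itself fell, namely SYK (-2.82), CD79B (-2.61) and BLK (-2.11). The pathway counted 9 higher and 20 lower of 31 (9 and 20 adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.147 with an estimated correlation). G1/S and replication genes counted 2 higher and 23 lower of 26 (2 and 23 adjusted over the list alone, camera adjusted p = 4.18e-06, adjusted p = 0.04998 with an estimated correlation), with E2F2 (-2.54) and CDT1 (-1.38). G2/M and mitosis genes counted 1 higher and 22 lower of 25 (1 and 22 adjusted over the list alone, camera adjusted p = 1.13e-04, adjusted p = 0.317 with an estimated correlation), with BIRC5 (-1.46) and PLK1 (-0.49). Higher with IgM were the plasma cell genes SLAMF7, from 20.9 ± 0.737 to 1019 ± 28.5 CPM (log2 5.61), and PRDM1 (2.90). Plasma cell genes counted 12 higher and 5 lower of 17 (12 and 5 adjusted over the list alone, camera adjusted p = 0.0464, adjusted p = 0.212 with an estimated correlation), and their call was lost without replicate 2 of WT untreated (0.0523) or replicate 3 of Y691F untreated (0.0507). MHC class II genes counted 11 higher and 4 lower of 15 (11 and 4 adjusted over the list alone, camera adjusted p = 0.00222, adjusted p = 0.170 with an estimated correlation), with HLA-DQB1 (3.18), HLA-DQA1 (2.43) and HLA-DRB1 (2.38). Cholesterol genes counted 17 higher and 3 lower of 21 (17 and 3 adjusted over the list alone, camera adjusted p = 1.03e-04, adjusted p = 0.0966 with an estimated correlation), with INSIG1 (2.36) and DHCR7 (1.42). The glycolysis and hypoxia genes SLC2A3 (4.42), VEGFA (2.69) and HK2 (1.73) rose. Their list counted 16 higher and 8 lower of 26 (16 and 8 adjusted over the list alone, camera adjusted p = 0.0464, adjusted p = 0.613 with an estimated correlation), a call lost without replicate 2 of WT untreated (0.0536) or replicate 3 of Y691F with IgM (0.0527). Cytokines and their receptors counted 18 higher and 5 lower of 23 (18 and 5 adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.173 with an estimated correlation). In the interferon response OAS3 rose (2.75) and BST2 fell (-2.56), without a call (5 higher and 8 lower of 16, with 5 and 8 adjusted over the list alone, camera adjusted p = 0.784). Cytosolic ribosomal protein genes counted 24 higher and 1 lower of 30 (24 and 1 adjusted over the list alone, camera adjusted p = 1.07e-04, adjusted p = 0.409 with an estimated correlation), RPL10 among them at 0.49.

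The largest rises with IgM in WT were the chemokine receptor gene CCR7, from 1.97 ± 0.308 to 975 ± 21.9 CPM (log2 8.94, adjusted p = 1.71e-99), and PDCD1, the gene of the checkpoint receptor PD-1 (8.14). The chemokine gene CCL3, which can share reads with its copies, rose from 0.917 ± 0.410 to 355 ± 5.25 CPM (log2 8.53). The phosphatase gene DUSP4 had 1 read in untreated WT and a ratio of 898 (161 to 35519), and the connexin gene GJA3 had 1 read and a ratio of 391 (69.8 to 15502). Both reads lay in replicate 1 of untreated WT, without which the rises were at least 203 and 88.6-fold. Without a read in untreated WT, the rise was at least 70.0-fold for TRPM4, 55.4-fold for DGKI, 48.5-fold for PPARGC1A, 46.9-fold for ADAMTS3 and 46.6-fold for BSND. The largest falls were in NAV2, from 57.9 ± 0.717 to 0.756 ± 0.184 CPM (log2 -6.26), OLFML2A (-5.51), NLRP7 (-5.17), SYT9 (-5.10) and PDZRN4 (-4.98) and the light chain segment IGLV6-57 (-5.62), whose reads can be split with other segments. ADGRB2 fell by 5.08, and without replicate 3 of WT with IgM, which left 1 read there, the ratio of untreated over IgM was 125 (22.1 to 4948). PRR15L had no read in WT with IgM and was at least 39.0-fold lower, while the ratios of untreated over IgM were 85.8 (23.4 to 713) for PRELP with 2 reads and 43.3 (14.5 to 212) for CDC42BPB with 3 reads. All 3 lay in replicate 2 of WT with IgM, and CDC42BPB was at least 27.6-fold lower without it. IgM raised 5809 genes and lowered 5814 in WT, 1346 and 2393 of them at least 2-fold, and with library totals only the split was 4642 and 6776.

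**Figure D3:**
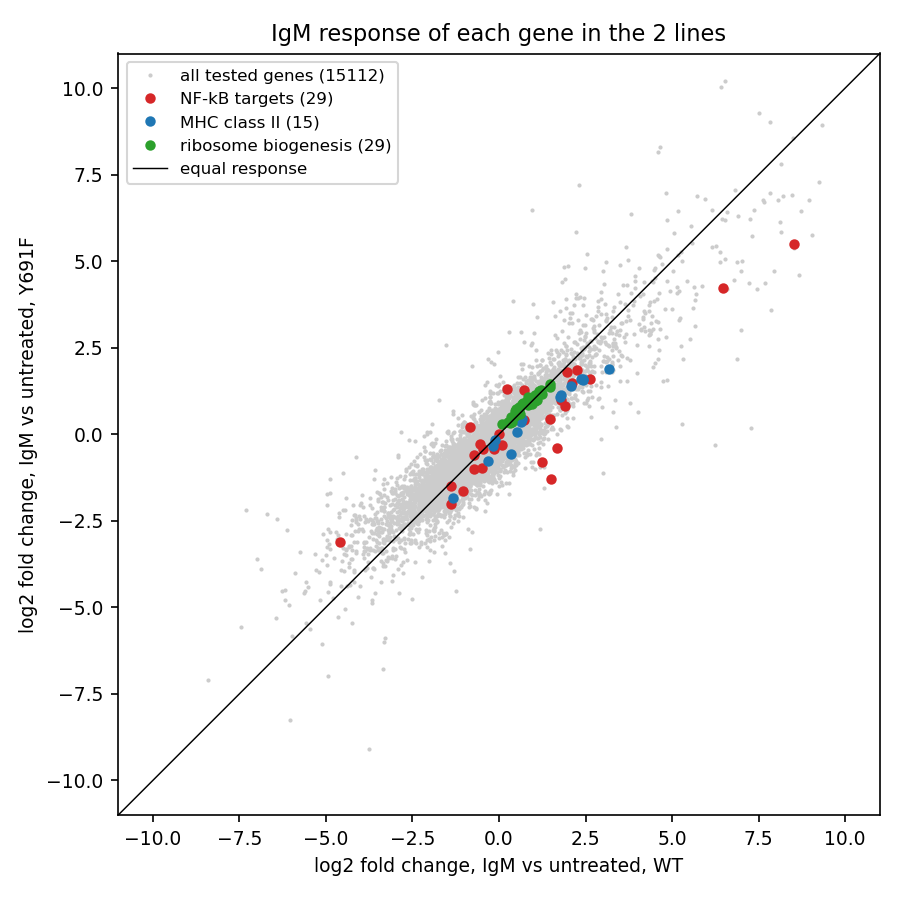
Log2 fold change with IgM in Y691F (vertical axis) against that in WT (horizontal axis), 1 grey point per tested gene, with NF-kB targets in red, MHC class II genes in blue, ribosome biogenesis genes in green and a line of equal response. Across 15112 genes Pearson's r was 0.910, and TNFAIP3 rose by 1.92 in WT and 0.81 in Y691F.

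The response of Y691F cells to IgM shared most of its genes with that of WT. EGR1 rose from 18.2 ± 2.06 to 334 ± 10.7 CPM (log2 4.20, adjusted p = 9.64e-79) and NR4A1 from 81.0 ± 4.52 to 1214 ± 24.2 CPM (log2 3.91). Immediate early genes counted 21 higher and 2 lower of 24 (21 and 2 adjusted over the list alone, camera adjusted p = 6.02e-08, adjusted p = 0.0460 with an estimated correlation). Ribosome biogenesis genes counted 29 higher and 0 lower of 29 (29 and 0 adjusted over the list alone, camera adjusted p = 1.71e-11, adjusted p = 0.0340 with an estimated correlation), with NPM1 at 1.25 and LYAR at 1.44. G1/S genes counted 1 higher and 23 lower of 26 (1 and 23 adjusted over the list alone, camera adjusted p = 4.18e-06, adjusted p = 0.04998 with an estimated correlation), with E2F2 at -2.07. G2/M genes counted 2 higher and 20 lower of 25 (2 and 20 adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.412 with an estimated correlation), with BIRC5 at -1.29. Germinal center genes counted 5 higher and 16 lower of 21 (5 and 16 adjusted over the list alone, camera adjusted p = 9.99e-04, adjusted p = 0.04998 with an estimated correlation). In that list CD27 fell (-2.77) and LMO2 rose (3.69). SYK (-2.43) and CD79B (-2.62) fell. B cell receptor signalling counted 9 higher and 20 lower of 31 (9 and 20 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.149 with an estimated correlation). INSIG1 (1.84) and SQLE (1.54) rose, and the cholesterol list counted 18 higher and 1 lower of 21 (18 and 1 adjusted over the list alone, camera adjusted p = 6.41e-06, adjusted p = 0.0627 with an estimated correlation). DDIT3 (3.75) and HSPA5 (1.95) rose. The unfolded protein response counted 20 higher and 3 lower of 23 (20 and 3 adjusted over the list alone, camera adjusted p = 3.80e-06, adjusted p = 0.203 with an estimated correlation). SLC2A3 (4.44) and VEGFA (3.34) rose. Glycolysis and hypoxia genes counted 19 higher and 2 lower of 26 (19 and 2 adjusted over the list alone, camera adjusted p = 5.09e-04, adjusted p = 0.352 with an estimated correlation). Cytosolic ribosomal protein genes counted 24 higher and 4 lower of 30 (24 and 4 adjusted over the list alone, camera adjusted p = 3.11e-04, adjusted p = 0.430 with an estimated correlation).

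NF-kB targets went both ways in Y691F with IgM (14 higher and 14 lower of 29, with 14 and 14 adjusted over the list alone, camera adjusted p = 0.739), with rises of CCL3 (5.50) and NFKB1 (1.86). The reported Roquin targets counted 6 higher and 4 lower of 13 (6 and 4 adjusted over the list alone, camera adjusted p = 0.272), with REL at 1.79. TNFAIP3 rose by 0.81 (adjusted p = 2.04e-29) and RC3H1 by 0.45, and for KLHL6 no change was called (0.048, adjusted p = 0.116), but a fall was with library totals only (-0.12, adjusted p = 6.05e-05). CCR7 (6.78), SLAMF7 (3.64) and HLA-DRB1 (1.59) rose. The largest rise with reads in both groups was VGF, from 0.473 ± 0.0710 to 301 ± 24.5 CPM (log2 9.28, adjusted p = 2.76e-77). Without a read in untreated Y691F, the rise was at least 160.4-fold for ARAP3, 144-fold for FOXA1 and 70.5-fold for TGM2, and DUSP4 with 2 reads had a ratio of 585 (162 to 4838). Among the largest falls were NLRP7 (-4.78) and AATBC (-4.78) and LINC00282, which fell by 4.70. Without replicate 3 of Y691F with IgM, which left 2 reads there, its ratio of untreated over IgM was 48.4 (13.2 to 403). KCNA2 had no read in Y691F with IgM and was at least 63.7-fold lower, and PRR15L with 1 read had a ratio of untreated over IgM of 184 (32.7 to 7307), and was at least 39.5-fold lower without the library of that read, replicate 2 of Y691F with IgM. IgM raised 5600 genes and lowered 5853 in Y691F, 1220 and 2173 of them at least 2-fold. With library totals only the split was 4245 and 7265.

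The interaction tested whether the response to IgM differed between the cells with Y691F and those with WT Roquin2. A negative value means that the log2 change with IgM was lower in Y691F, as a smaller rise, a deeper fall, or a fall where WT rose. TNFAIP3 had an interaction of -1.11 (SE 0.06, adjusted p = 3.66e-27). The cytokine genes LTA (ENSG00000226979, chromosome 6, 31572054 to 31574324, plus strand) and TNF (ENSG00000232810, chromosome 6, 31575567 to 31578336, plus strand) had interactions of -2.10 (SE 0.07, adjusted p = 5.29e-43) and -2.03 (SE 0.08, adjusted p = 1.28e-38). LTA went from 34.4 ± 1.64 to 111 ± 5.23 CPM in WT and from 43.0 ± 0.845 to 32.5 ± 0.231 CPM in Y691F, and TNF from 26.9 ± 1.495 to 63.8 ± 1.35 and from 42.7 ± 1.90 to 24.7 ± 1.69 CPM. The IkB genes NFKBID (-1.17) and NFKBIE (-1.03), the survival gene BCL2A1 (-1.04) and IRF4 (-0.51) were also negative. NF-kB targets counted 5 positive and 19 negative of 29 (5 and 20 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 5.16e-07, adjusted p = 0.0460 with an estimated correlation). Reported Roquin targets counted 1 positive and 8 negative of 13 (1 and 10 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 3.78e-07, adjusted p = 0.0460 with an estimated correlation). Among immediate early genes EGR1 (-2.39), EGR3 (-2.45) and NR4A3 (-1.90) were negative. The list counted 3 positive and 17 negative of 24 (3 and 17 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 6.25e-08, adjusted p = 0.0460 with an estimated correlation). MHC class II genes counted 0 positive and 13 negative of 15 (0 and 13 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 3.44e-12, adjusted p = 0.0340 with an estimated correlation). They included HLA-DQB1 (-1.29), HLA-DQA1 (-0.85), HLA-DRB1 (-0.78) and HLA-DRA (-0.67). Cytokines and their receptors, of which 6 are on the NF-kB list, counted 2 positive and 14 negative of 23 (3 and 17 adjusted over the list alone, camera adjusted p = 3.34e-07, adjusted p = 0.0550 with an estimated correlation), with IL10RA at -0.88. Plasma cell genes counted 4 positive and 9 negative of 17 (4 and 9 adjusted over the list alone, camera adjusted p = 0.0120, adjusted p = 0.141 with an estimated correlation), with SLAMF7 at -1.97 and FCRL5 at -1.37.

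Among positive interactions, BCL6 fell less in Y691F (0.82, adjusted p = 3.67e-28), as did CD38 (0.87) and BLK (0.82), and the phosphatase gene PTPN6 rose more (0.89). B cell receptor signalling counted 16 positive and 7 negative of 31 (16 and 8 adjusted over the list alone, camera adjusted p = 0.0110, adjusted p = 0.141 with an estimated correlation). Germinal center genes counted 9 positive and 6 negative of 21 (9 and 6 adjusted over the list alone). KLHL6 had an interaction of 0.76 (adjusted p = 1.11e-28), RC3H1 of -0.48 (adjusted p = 2.99e-07) and RC3H2 of -0.15 (adjusted p = 0.00914). G1/S genes counted 9 positive and 1 negative of 26 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0271, adjusted p = 0.255 with an estimated correlation), PCNA among them at 0.30. Their list call was lost with library totals only, a scaling that moved the median interaction over all genes by -0.036. Ribosome biogenesis genes counted 10 positive and 0 negative of 29 (11 and 0 adjusted over the list alone), with ODC1 at 0.24. T and NK cell markers counted 2 positive and 0 negative of the 5 tested out of 16 on the list (2 and 0 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.112 with an estimated correlation), with TRAC at 0.46. By size, the largest positive interactions were CPED1 (3.46), RTN4R (2.80), GATA4 (2.76) and SLC7A8 (2.71) and C10orf54 (2.89, or 3.74 without replicate 1 of WT with IgM). The largest negative ones were the heat shock genes HSPA6 (-4.98) and HSPB1 (-3.16), the collagen chaperone gene SERPINH1 (-3.39) and CCL3 (-3.03). The interaction was positive in 2217 genes and negative in 1666, and 222 and 186 of these differed at least 2-fold. With library totals only the split was 1846 and 2134. Median, mean and camera direction of a list differed in sign, each time without a call, for p53 targets in 3 contrasts (Y691F against WT with IgM and untreated, and IgM in Y691F), and for reported Roquin targets, the unfolded protein response and the T and NK cell markers in the untreated comparison. They also did for mitochondrial mRNAs with IgM in Y691F and in the interaction, and for the BCL2 family and glycolysis and hypoxia in the interaction.

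**Figure D4:**
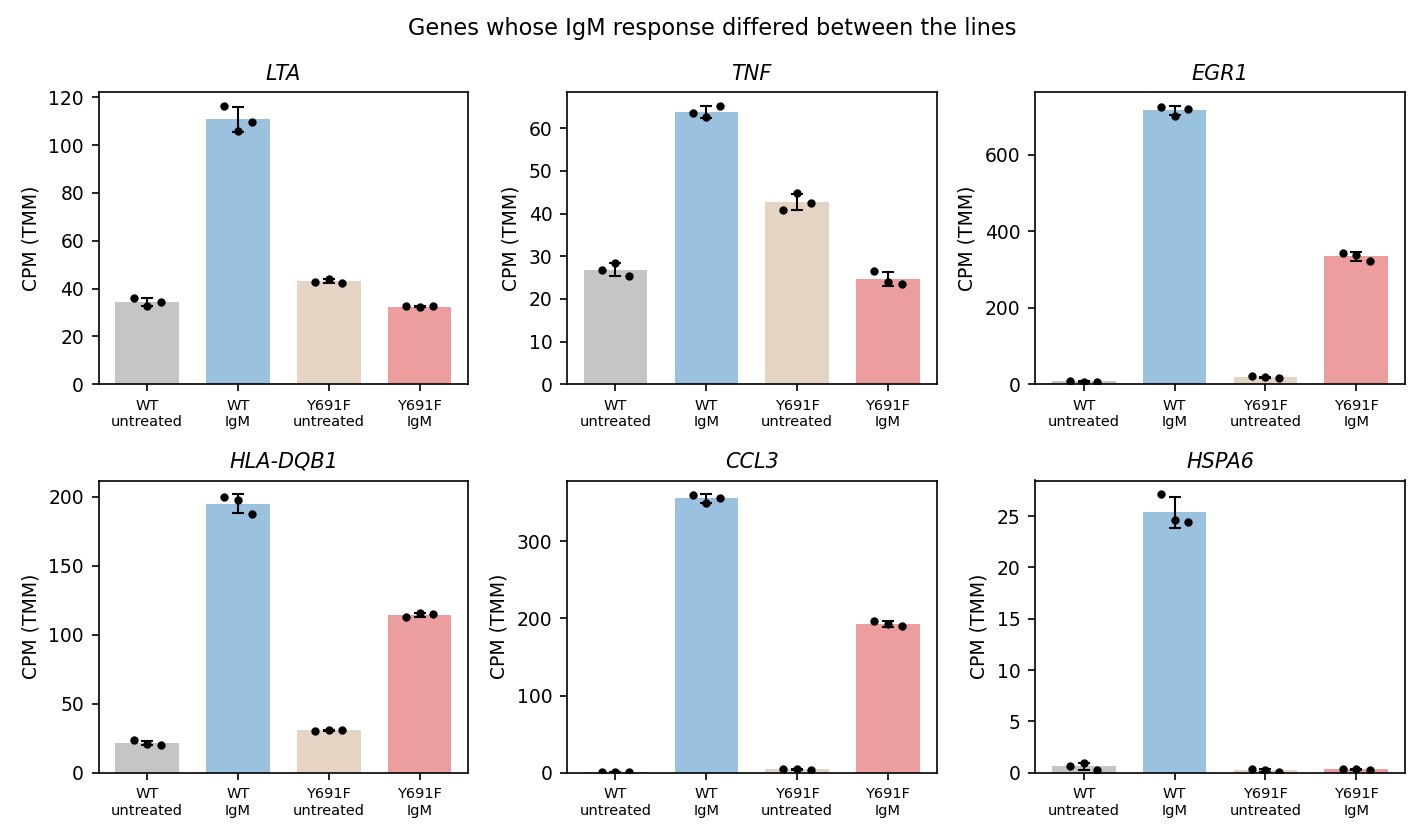
Levels in CPM (TMM-scaled) of genes with a called interaction in the 4 groups, where bars are means, points are the 3 libraries and error bars are the SD. LTA reached 111 CPM with IgM in WT and 32.5 CPM in Y691F, and EGR1 716 and 334 CPM.

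Across genes, which are not independent replicates, the IgM responses of WT and Y691F had a Pearson's r of 0.910 and a Spearman's rho of 0.904, with no library in common. Both responses were called higher for 4904 genes (2153 if the calls were independent), both lower for 5002 (2252) and opposite for 216 (4404). Of the genes called in opposite directions, each with a called interaction, 108 rose in WT and fell in Y691F and 108 did the reverse. The differences between Y691F and WT with and without IgM had an r of 0.471 and a rho of 0.347, again without shared libraries. Both were higher for 1305 genes (498 if independent), both lower for 1097 (493) and opposite for 538 (994). RC3H2 and the cholesterol gene HMGCS1 were among those higher in Y691F in both states, VEGFA was lower in both, and EGR1, TNF and SLAMF7 were higher untreated and lower with IgM.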

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

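The test of the NF-kB pattern on all mRNAs with the stem-loop motif was chosen before its result was seen, whereas the counts of NF-kB list members and reported Roquin targets with the motif, the tests of damping and of untreated levels, the tests on heat shock genes and the splits of the libraries were chosen only after the results were seen. The responses to IgM differed between the WT and Y691F cells by a test of that difference, with 2217 genes positive and 1666 negative. Negative interactions included those of TNFAIP3 (-1.11), LTA (-2.10), TNF (-2.03), NFKBID (-1.17), BCL2A1 (-1.04), NFKBIE (-1.03) and IRF4 (-0.51) among NF-kB and reported Roquin targets, EGR3 (-2.45), EGR1 (-2.39) and NR4A3 (-1.90) among immediate early genes, and HLA-DQB1 (-1.29), HLA-DQA1 (-0.85), HLA-DRB1 (-0.78) and HLA-DRA (-0.67) of MHC class II. SLAMF7 (-1.97), FCRL5 (-1.37), IL10RA (-0.88), CCL3 (-3.03), RC3H1 (-0.48) and RC3H2 (-0.15, a call lost with a minimum fold of 1.2) were negative as well, as were HSPA6 (-4.98), SERPINH1 (-3.39) and HSPB1 (-3.16). Positive interactions included CPED1 (3.46), RTN4R (2.80), GATA4 (2.76) and SLC7A8 (2.71), and C10orf54 (2.89, or 3.74 without replicate 1 of WT with IgM). Also positive were PTPN6 (0.89), CD38 (0.87), BLK (0.82), BCL6 (0.82) and KLHL6 (0.76), and by smaller amounts TRAC (0.46), PCNA (0.30) and ODC1 (0.24).

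Of the gene lists, the median interaction was -0.67 for MHC class II, -0.64 for immediate early genes, -0.49 for cytokines and their receptors, -0.45 for reported Roquin targets, -0.38 for NF-kB targets and -0.20 for plasma cell genes. It was 0.49 for T and NK cell markers (5 of 16 tested), 0.18 for B cell receptor signalling, 0.12 for germinal center genes, 0.092 for ribosome biogenesis and 0.084 for G1/S genes. The call for G1/S genes was lost with library totals only. The call for ribosome biogenesis (camera adjusted p = 0.03997, adjusted p = 0.339 with an estimated correlation) was lost without replicate 2 of WT untreated (0.0629), replicate 1 of WT with IgM (0.0765), replicate 1 (0.0609) or 3 (0.0507) of Y691F untreated, or replicate 3 of Y691F with IgM (0.0579). The call for germinal center genes (camera adjusted p = 0.0464, adjusted p = 0.161 with an estimated correlation) was lost without replicate 2 of WT with IgM (0.0567), replicate 1 (0.0545) or 2 (0.0586) of Y691F untreated, or replicate 2 (0.0592) or 3 (0.0707) of Y691F with IgM. Of 100 splits drawn from the 200 possible, 2 gave as many called interactions as the real 3883, the real one included. The other, with 6693 genes, crossed the WT and Y691F labels in the IgM libraries, which turns the interaction into the sum of both differences between the lines and so reflects a structure of the samples. The next highest split gave 2873 genes, and the median of the other splits was 0. Splits that mix WT and Y691F libraries move the difference between the lines into the spread. They tend to call few genes with or without an interaction, so the splits cannot decide on a chance division of the libraries.

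The first pattern weighed was the lower response of TNFAIP3 and other NF-kB targets to IgM in Y691F. The median residual of the NF-kB list from the line through all genes was -0.35. It lay outside the -0.17 to 0.13 that held 95% of 10000 random lists matched on the WT response. This argues against a damping equal for all genes as the whole account for the list, with 2 limits. The list was weighed because its interaction was already negative. The random lists also ignore the correlation between its members, estimated at 0.05, so their interval is likely too narrow. A general damping stays open for immediate early genes, whose median residual of -0.29 lay within their -0.37 to 0.15. A higher untreated level was argued against for TNFAIP3, which differed by -1.01 with IgM, but stays open for the list, whose median with IgM was -0.20 (bootstrap 95% interval -0.53 to 0.03). The Roquin stem-loop motif in the 3' UTR was searched by sequence without folding. Over 764 of 11459 mRNAs with the motif, a wider set than the pattern, the median difference was -0.0151 (-0.03997 to 0.000279, permutation p = 0.18). A control motif gave -0.0391 (permutation p = 0.0015, adjusted p = 0.009 over 6 tests), so a shift of that size also arose without the stem-loop motif. These values argue against a large shift of all mRNAs with a sequence match. They cannot decide on the motif as the cause of the pattern, because the search found no match in TNFAIP3. Of the 19 NF-kB list members with a negative interaction, a count made after both of those results were known, 2 carried the motif (NFKBIZ and TNF), or 10.5% (exact 95% interval 1.30 to 33.1) beside 6.67% of all mRNAs searched, and of the 13 reported Roquin targets 5 carried it, 3 of these with a negative interaction (NFKBID, NFKBIZ and TNF) against 5 of the 8 without it, and as the other 8, TNFAIP3 among them, lacked it, a direct action of Roquin2 on TNFAIP3 and the other targets stays open. The Roquin2 form, its 1.70-fold higher RC3H2 level with IgM, its effect through other regulators and other differences between the cells remain as untested explanations, which this design does not separate.

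The second pattern weighed was that of heat shock genes, from a list of 20 genes written after the data were seen. Of 19 tested members, 14 were lower and 3 higher in Y691F than in WT with IgM, 12 rose and 5 fell with IgM in WT, and 4 rose and 8 fell in Y691F, with DNAJB1 at 115 and 274 CPM in WT and 103 and 85.8 CPM in Y691F without and with IgM. A single stressed library would have to be shifted from the other 2 of its group by at least the interaction (a slope of 1 or more over all 19 members). The slope farthest from 0 among the 6 libraries with IgM was 0.0736 (bootstrap 95% interval -0.0414 to 0.0961), which argues against a single stressed library. Other criteria for this explanation, also written after the data were seen, are not reported here. A difference already there without IgM stays open for the set, since 12 members were lower and 0 higher in untreated Y691F and the median interaction was -0.048 (-1.53 to 0.0039). Cultures of a whole group handled apart, for example at another temperature, cannot be told apart from an effect of the Roquin2 form, as 0 libraries separate handling from group, and HSPA1A, HSPA1B and HSPA6 have near-identical copies.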

How the results depend on the processing

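Scaling by library totals only was chosen after the data were seen, and the other alternatives before. Over them, 4846 of 4857 values of named genes, 966 of 1044 calls of single lists and 110 of 114 counts of genes kept their direction and their side of the threshold (or, for counts, stayed within 1.5 times). The named genes were picked in the same data, and 2568 of their values are refits without 1 library, so this stability was largely built in. With an estimated correlation 42 of 58 list calls were lost. Of 32 values of r between contrasts, 24 moved by more than the SE from leaving out each library. With a minimum fold of 1.2, the counts of called genes were 2028 for Y691F against WT with IgM, 1126 untreated and 1084 for the interaction, because small changes no longer pass, and RC3H2 was no longer called for IgM in WT (0.13, adjusted p = 1) or in the interaction (-0.15, adjusted p = 1). The same setting ended the calls of KLHL6 (adjusted p = 0.153) and HLA-DRB1 (0.453) for Y691F against WT with IgM, of FBL and E2F1 (both 1) untreated, and of PCNA (0.411), ODC1 (1) and TRAC (0.154) in the interaction. With the 7 libraries of barcode series b the interaction had 2558 genes and RC3H2 -0.15 (adjusted p = 0.105), with fewer libraries in the fit. With an estimated correlation 1, 3, 4, 4 and 4 lists were called in place of 12, 11, 14, 10 and 11, and fry, which does not compare a list with other genes, called 21 for IgM in Y691F. With a filter of 5 CPM, RC3H2 was called for IgM in Y691F (-0.074, adjusted p = 0.0182), KLHL6 there changed sign without a call (-0.0053), and r was 0.944 for the IgM responses and 0.501 for the differences between the lines, over fewer, more abundant genes. With library totals only, RC3H2 had -0.0051 for IgM in WT and -0.19 (adjusted p = 4.16e-08) in Y691F, KLHL6 -0.12 (a called fall, adjusted p = 6.05e-05) in Y691F, in keeping with the lower TMM factors of the IgM libraries. That setting gave RC3H1 -0.013 for Y691F against WT with IgM, a contrast whose median over all genes it moved by -0.016. Leaving out each library in turn gave 5563 to 6501, 3994 to 4806, 11190 to 11769, 11043 to 11583 and 3384 to 3828 called genes in the 5 contrasts, r of 0.894 to 0.902 and 0.438 to 0.458 for both agreements, and -0.058 (without replicate 1 of WT with IgM) to 0.070 for RC3H1 in Y691F against WT with IgM. The main r of 0.910 and 0.471 and the main interaction count of 3883 lay outside these ranges. The low-count filter was run again in each of these fits, so the set of tested genes could change. Whether this or the missing library moved the values was not tested. The replicate numbers only share a name: over 18 same-number pairs the correlations of the deviations were -0.06 to 0.03, with 0 over 0.1, and 1 of 12 libraries correlated best with its own number. With the replicate block the counts were 6364, 4737, 11622, 11452 and 3898, and the list calls for plasma cell genes with IgM in WT (0.0563) and germinal center genes in the interaction (0.0509) were lost. With the barcode series as a covariate 4 list calls were lost: replication histones for Y691F against WT with IgM (0.0604), glycolysis and hypoxia with IgM in WT (0.0502), and ribosome biogenesis (0.0536) and germinal center genes (0.0604) in the interaction. With library totals only 5 were lost: cytosolic ribosomal proteins untreated (0.0838), glycolysis and hypoxia with IgM in WT (0.0764), and ribosome biogenesis (0.116), G1/S (0.0696) and germinal center genes (0.0510) in the interaction. The alternative pseudocount was not run because the values are counts. Depth limits the ratios of genes with 0 to 3 reads in a group.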

Other observations

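The tests on regional windows, on GC content and length, and on the stem-loop motif in the untreated cells were chosen before their results were seen, and the splits of the libraries after. HSPA1A and HSPA1B, a pair of near-identical heat shock genes named here after their values were seen, were among the 108 genes that rose with IgM in WT and fell in Y691F. HSPA1A went from 58.7 to 113 CPM in WT and from 41.0 to 21.3 CPM in Y691F, and HSPA1B from 363 to 616 and from 266 to 136 CPM.

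The third pattern weighed was that many genes, such as GNAZ and INSIG1, already differed between the untreated WT and Y691F cells. Windows of 20 neighbouring called genes explained 4.36% (2.60 to 5.81) of the variance of their fold changes, a small share but above the highest of 200 permuted values, 1.44%. This argues against regional DNA copy number as the source of most of that variance. Small shifts, or shifts confined to a few regions, stay open. GC content and length were argued against as the source of most of it too (0.725%, 0.332 to 1.54, over 4275 of 4716 genes, or 90.6%). mRNAs with the Roquin stem-loop motif, 764 of 11459, differed from others of like UTR length by 0.00363 (-0.0135 to 0.0187, permutation p = 0.55) on the log2 scale, so no shift was found for them as a set. The search by sequence without folding found the motif in 5 of 13 reported Roquin targets and not in TNFAIP3. It therefore cannot decide on a direct action of Roquin2 on mRNAs without a match. A mixture of subclones, with or without copy number change in a few regions, the Roquin2 form and the dose of RC3H2 stay open and were not tested. Other splits of the 6 libraries of a comparison, 10 each, are too few for a share under 0.05. The real split, 1 of 10, was the only one to give as many genes in Y691F against WT with IgM (6362, highest other 0), Y691F against WT untreated (4716, highest other 0), IgM in WT (11623, highest other 0) and IgM in Y691F (11453, highest other 0).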
